A study of Mus musculus with 23 samples.

How the data were processed

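RNA was sequenced from 23 mouse libraries in 5 groups: cultured control and N1OE progenitors, and re-isolated control, N1OE and N1KO cells labelled as donor-derived. Per the labels' protocols, cultured cells were extracted with Trizol and made into TruSeq stranded mRNA libraries, and re-isolated cells were lysed in Buffer RLT, purified on beads and made into libraries with NEBNext low-input cDNA and Nextera XT. Setting and kit are therefore joined, and no comparison across settings is free of the kit. Groups were taken from the sample titles. A mark, the suffix GoF, in the column headers of 5 of the 9 re-isolated controls is not explained in the labels. The descriptions carry it too, except for control replicate 7.

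Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.33, checked with FastQC, counted with featureCounts and normalised with edgeR on the mm10 genome. The aligner and the gene annotation were not given in the sources used here. The values deposited by the authors are log2 CPM with a small prior count, in a table of 21264 genes. The lowest value, -4.19 in log2, stands for 0 reads. Whole reads were recovered from the steps between values in all libraries (tolerance 0.05 reads). Whether they were adjusted before deposit was not decided. Counting intervals, bounds and limma-voom take them as raw. The sources used here give no reads in other forms, and raw reads were not analysed here. Library totals were 11637817 to 29154176 reads in the listed genes, so that 3 reads stand for 0.258 CPM in the smallest and 0.103 CPM in the largest library. Of the gene IDs 21186 were found in GENCODE M21, from which the coordinates (GRCm38/mm10) were taken.

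The deposited log2 values were used as they stand. The plan had named log2(CPM + 1) for a file of CPM and the values themselves for a file of log2 CPM, so a pseudocount of 1 became an added alternative. Genes with at least 1 CPM in at least 3 libraries of a fit were tested with limma (eBayes with a trend, two-sided), and p-values were adjusted after Benjamini-Hochberg with a threshold of 0.05. The cultured groups were fitted alone. The 3 re-isolated groups shared 1 fit, from which N1OE against control, N1KO against control and N1OE against N1KO were taken. Re-isolated and cultured controls were fitted alone, and all 5 groups were fitted together for the difference between the N1OE effects. A fold against a group with 0 reads is a lower bound that sets 3 reads over that group. With 1 to 3 reads the ratio of counts is given with a 95% interval that holds counting error only. Errors of log2 fold changes are standard errors of limma.

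Fixed gene lists were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. The program lists are Notch target genes, Notch receptors, ligands and regulators, satellite cell markers, quiescence genes, myogenic regulators, sarcomere and contractile genes, myosin heavy chains, premyogenic mesoderm genes, cell cycle genes, embryonic and fetal growth genes, pluripotency genes, extracellular matrix genes, immediate early and dissociation stress genes, interferon response genes, oxidative phosphorylation genes, glycolysis genes, p53 targets, cytosolic ribosomal protein genes and mitochondrially encoded genes. The cell type lists are endothelial, pericyte and smooth muscle, fibro-adipogenic, macrophage, lymphocyte and neutrophil, Schwann and glial, neuronal, tenocyte and chondrocyte, and erythroid markers. Lists with fewer than 3 measured genes were not tested.

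Genes are named by a rule. Per comparison it takes Notch1 and every measured Notch target, the 8 largest rises and 8 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted genes, and up to 4 members of each list with the smallest p. Where fewer than 3 genes passed in a direction the 5 with the smallest p were taken. For the difference between N1OE effects the overlap condition was not applied, since 4 groups enter it. Of the genes the rule takes from the lists at most about 2 per list are printed, and Notch targets that did not pass are mostly given as a count.

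The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other pseudocounts, other filters, median ratio scaling, array weights, replicate numbers as a block, leaving out each library in turn, an estimated correlation for the lists and fry. Also planned were the control sets by description, description numbers as a block, fits of 2 groups alone and separate fits for the difference of effects. Added after the data were seen were limma-voom on the recovered reads, a pseudocount of 1, the 2 sets of re-isolated controls by column header, the forms of description in the cultured libraries, and, for the gene lists, median ratio scaling and leaving out each library.

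The pipeline was tested on data simulated from these libraries, with 67, 67 and 66 genes changed by 1, 2 and 4 in log2. Of these, 40.3, 88.1 and 98.5 percent were called for cultured N1OE, 16.4, 76.1 and 98.5 for re-isolated N1OE, and 14.9, 70.2 and 100 for N1KO. The shares were 2.99, 59.7 and 100 for N1OE against N1KO, 37.3, 79.1 and 95.5 for re-isolated against cultured controls, and 7.46, 55.2 and 93.9 for the difference of effects. Calls of unchanged genes numbered 11, 7, 16, 13, 7 and 5 in the same order. Other splits of the libraries gave up to 2618 (below), so these do not bound false calls. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.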

Results

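Bulk RNA sequencing was carried out on 23 mouse libraries of iPax3 cells, a pluripotent stem cell line in which induced expression of Pax3, a transcription factor of the muscle lineage, yields myogenic progenitors. Of these, 7 libraries came from progenitors in culture (4 control and 3 N1OE) and 16 from cells labelled as donor-derived satellite cells, the stem cells of skeletal muscle, re-isolated after engraftment (9 control, 4 N1OE and 3 N1KO). N1OE cells overexpress NICD1, the intracellular domain of the Notch1 receptor, and N1KO cells carry a Notch1 knockout. Reads in the listed genes numbered 15273185 to 21761905 in the cultured controls and 15890351 to 20201265 in cultured N1OE. They numbered 16501661 to 28941840 in re-isolated controls, 11637817 to 29154176 in re-isolated N1OE and 17789927 to 18621838 in N1KO. Levels are given as CPM, the reads of a gene scaled to the total of its library. One read was worth 0.0859 CPM in the smallest library and 0.0343 CPM in the largest. The labels do not state whether replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Cultured N1OE replicates 2 and 3 differed from each other by a chi-square per degree of freedom of 3.43, against 31.3 and 36.8 for the other pairs of that group and 50.9 to 164 for pairs of cultured controls.

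The re-isolated control libraries fell into 2 sets that the deposited table itself separates. Its column headers carry a mark, the suffix GoF, in 5 of them (replicates 1, 4, 7, 8 and 9, called marked below). The other 4 carry none (replicates 2, 3, 5 and 6, called unmarked). The 4 cultured controls and cultured N1OE replicate 1 carry it too. The labels do not explain the letters, while the series text speaks of Notch1 gain of function. Between the sets 3645 of 13230 tested genes differed, 1797 higher and 1848 lower in the marked libraries. Sarcomere and contractile genes were lower in the marked set (adjusted p = 2.7e-10 by camera) and so were Notch target genes (0.00063) and myogenic regulators (0.000195), while cell cycle genes (3.5e-06) and extracellular matrix genes (1.7e-07) were higher. Immediate early and dissociation stress genes (0.000224), glycolysis genes (1.6e-07), cytosolic ribosomal protein genes and mitochondrially encoded genes (8.97e-05 each) were lower as well, and fibro-adipogenic (0.000996) and macrophage markers (0.0178) were higher. Ddx3y, a gene of the Y chromosome, lay between 0 and 2.77 CPM in the unmarked controls and between 38.5 and 171 CPM in the marked ones. In N1KO it lay between 26.9 and 77.2 CPM. Ddx3y reads depend on the cells as well as on the library, so they do not show which set N1KO belongs to. The ratio of genes with 1 read to genes with 2 reads was 1.08 to 1.5 in the unmarked controls and 1.25 to 1.40 in N1KO, against 4.17 to 5.91 in the marked controls and 4.18 to 6.82 in re-isolated N1OE. Each comparison with the re-isolated controls is therefore given over all 9 libraries and within each set.

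**Figure D1:**
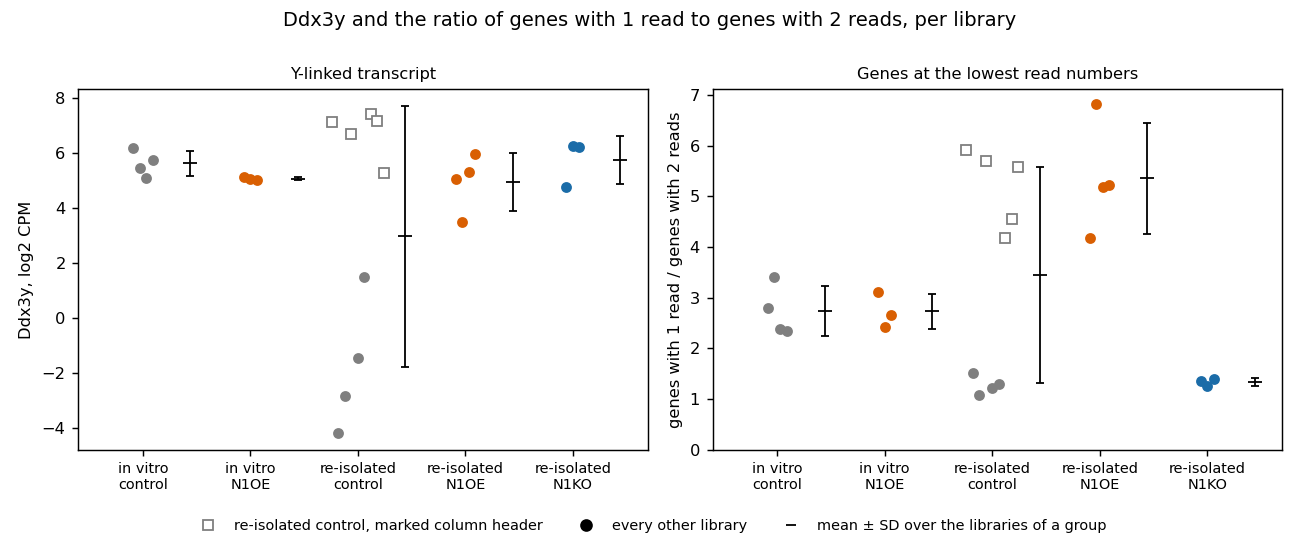
Log2 CPM of Ddx3y (left) and the number of genes with 1 read divided by the number with 2 reads (right), 1 point per library with the mean and SD of each group. The 4 unmarked control libraries (filled grey points of the re-isolated controls) lie at or below 2.77 CPM of Ddx3y, and their read ratios (1.08 to 1.5) overlap those of N1KO (1.25 to 1.40).

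Notch1 (chromosome 2, 26457903 to 26516663, GRCm38/mm10) was read in every library. In culture it measured 61.4, 78.4, 71.0 and 105 CPM in the 4 controls and 370, 298 and 322 CPM in the 3 N1OE libraries. Re-isolated controls 1 to 9 measured 14.9, 136, 174, 88.9, 156, 150, 27.5, 52.0 and 72.9 CPM. Re-isolated N1OE 1 to 4 measured 247, 257, 151 and 98.1 CPM, and N1KO 1 to 3 measured 15.6, 19.8 and 52.6 CPM. Reads over the whole gene do not show which part was deleted or which part was overexpressed, so the level checks the knockout label only in part: control replicate 1 lay below all 3 N1KO libraries, and N1KO replicate 3 lay above control replicates 1, 7 and 8.

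**Figure D2:**
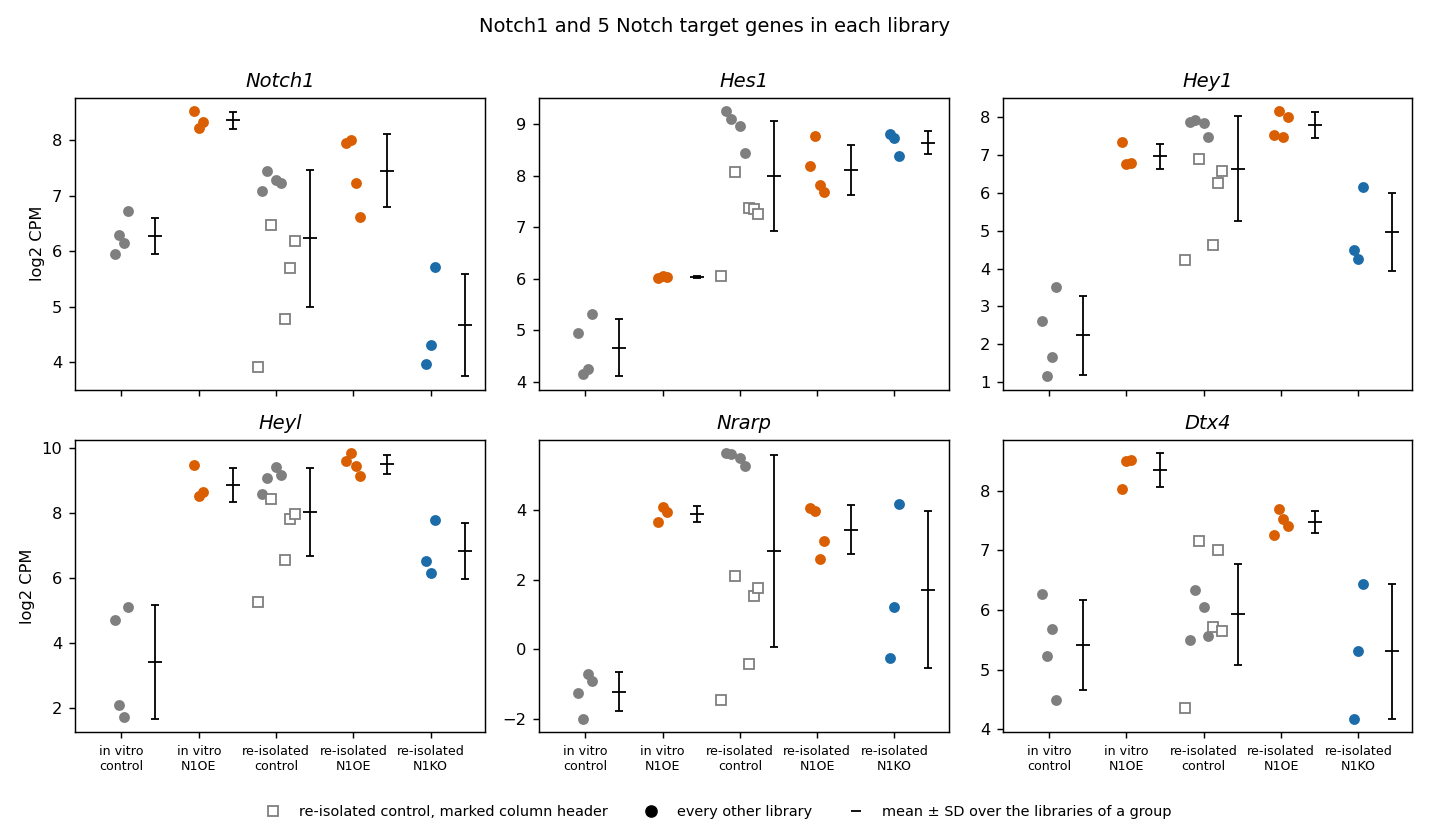
Log2 CPM of Notch1 and of the Notch target genes Hes1, Hey1, Heyl, Nrarp and Dtx4, 1 point per library with the mean and SD of each group. In culture every N1OE library lies above every control for all 6 genes (Hey1: 127 against 5.66 CPM), whereas among the re-isolated libraries the controls span the N1OE range for Hes1 and Nrarp.

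The first comparison asked what NICD1 changes in cultured progenitors. Notch target genes rose and genes of the contractile apparatus fell. Notch1 itself was higher by a log2 fold change of 2.08 ± 0.18 (SE, adjusted p = 0.00244; 330 ± 36.8 against 79.0 ± 18.9 CPM, mean ± SD, n = 3 and 4). Of 10 measured Notch target genes 6 rose and none fell (7 and 1 when adjusted over the list alone, camera adjusted p = 0.00235, adjusted p = 0.637 with an estimated correlation). These were the transcriptional repressors Hey1 (chromosome 3, 8663359 to 8667256; 4.73 ± 0.54, adjusted p = 0.00489), Heyl (chromosome 4, 123233556 to 123249875; 5.48 ± 0.89, 0.0145) and Hes1 (chromosome 16, 30064384 to 30067796; 1.37 ± 0.29, 0.0300). The others were the Notch feedback regulator Nrarp (chromosome 2, 25180758 to 25183339; 5.10 ± 0.37, 0.00231), the ubiquitin ligase Dtx4 (2.93 ± 0.39, 0.00833) and the receptor Notch3 (1.63 ± 0.21, 0.00772). Hey2 (2.87, adjusted p = 0.0631), Lfng (0.81, 0.384), Bcl6 (-0.62, 0.125) and Gadd45g (-0.67, 0.153) did not pass. Leaving out N1OE replicate 1, 2 or 3 moved Heyl to an adjusted p of 0.0599, 0.0654 and 0.0693 and Hes1 to 0.0992, 0.126 and 0.126. Hes1 also missed the threshold without control replicate 2 (0.0630), and Dtx4 without N1OE replicate 2 (0.0549) or 3 (0.0535).

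Genes of muscle differentiation were lower in cultured N1OE. Of 23 sarcomere and contractile genes 8 fell and none rose (19 adjusted over the list alone, camera adjusted p = 4.91e-09, adjusted p = 0.696 with an estimated correlation). Among them was the myosin light chain Myl1 (15.6 ± 18.6 against 417 ± 332 CPM; log2 fold change -4.91 ± 1.03, adjusted p = 0.0298). Of 6 myosin heavy chain genes 1 fell, the embryonic Myh3 (-4.01 ± 0.99, adjusted p = 0.0451; 5 adjusted over the list alone, camera adjusted p = 0.00330, adjusted p = 0.696 with an estimated correlation). Among 15 myogenic regulators 6 fell (12 adjusted over the list alone, camera adjusted p = 7.74e-06, adjusted p = 0.637 with an estimated correlation). The determination factor Myod1 fell by 2.81 ± 0.55 (adjusted p = 0.0241) and the splicing factor Rbm24 by 2.45 ± 0.38 (0.0130). Of 20 satellite cell markers the adhesion gene Cdh15 rose (1.51 ± 0.25, 0.0162) with 1 other, and the intermediate filament gene Des fell (-3.66 ± 0.62, 0.0162, camera adjusted p = 0.214). Of 12 premyogenic mesoderm genes 4 rose, including Dmrt2 (2.08 ± 0.36, 0.0169) and Eya1 (0.87 ± 0.14, 0.0147, camera adjusted p = 0.322). Many of these calls were lost whichever N1OE library was left out, which leaves 2 in that group, and no direction turned. Without N1OE replicate 2 or 3 the adjusted p was 0.133 and 0.132 for Myl1, 0.177 and 0.178 for Myh3, 0.116 and 0.112 for Myod1, 0.0706 and 0.0723 for Rbm24. In the same fits it was 0.0764 and 0.0762 for Cdh15, 0.0839 and 0.0850 for Des, 0.0821 and 0.0804 for Dmrt2, and 0.0759 and 0.0822 for Eya1. Without N1OE replicate 1 it was 0.0562 for Myh3, 0.0534 for Myod1, 0.0647 for Cdh15, 0.0672 for Dmrt2 and 0.0639 for Eya1. Without control replicate 2 it was 0.0694 for Myl1, 0.0884 for Myh3 and 0.0502 for Myod1, and Myh3 also missed the threshold without control replicate 1 (0.0645) or 4 (0.0634). The myosin heavy chain list was lost without control replicate 1 or 4 (camera adjusted p up to 0.0592).

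The steepest rises in cultured N1OE were in Tfap2b, a neural crest transcription factor (44.3 against 0.0280 CPM; read ratio 1682, 95% counting interval 465 to 13900), the adrenergic receptor gene Adra1a (7.37 ± 0.60, adjusted p = 0.00232), the plakophilin gene Pkp1 (7.23 ± 0.84, 0.00512), the neuropeptide gene Gal (6.62 ± 0.25, 0.000211), the synaptic organiser Cbln1 (5.97 ± 0.74) and the protocadherin Pcdh8 (5.58 ± 0.73). The VEGF receptor gene Flt1 rose by the same measure (6.54 ± 1.18), as did the serine protease gene Fap (5.74 ± 1.08). Slc1a3, a glutamate transporter gene, had no read in N1OE and was at least 668-fold lower than in controls (35.9 ± 32.0 CPM; the bound uses 3 reads over the group). The matricellular gene Ccn3 fell by 7.97 ± 0.86, the transcription factor Hand1 by 7.76 ± 0.75, Nrn1 by 6.32 ± 0.47, the selectin gene Selp by 6.31 ± 0.55 and the osteoprotegerin gene Tnfrsf11b by 6.08 ± 0.59. Tgfbi (0.0585 against 38.7 CPM; read ratio 652, interval 223 to 3165) and the histone methyltransferase family gene Prdm6 (0.0165 against 8.68 CPM; 490, 87.7 to 19400) were also lower. Leaving out N1OE replicate 1, 2 or 3 gave adjusted p-values of 0.0770, 0.0803 and 0.0802 for Flt1 and 0.0865, 0.0910 and 0.0848 for Fap, and Tgfbi missed the threshold without N1OE replicate 2 (0.05001) or 3 (0.0615). The limit for Slc1a3 was 401-fold without control replicate 4 and 426 and 432 without N1OE replicate 1 and 3. The read ratio of Tgfbi was 160 without control replicate 4 and 1400 and 422 without N1OE replicate 2 and 3, and that of Tfap2b 2683 without control replicate 2. For Prdm6 it was 290 without control replicate 3, 317 without N1OE replicate 3 and at least 103 without N1OE replicate 1, which holds its read.

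Of 25 immediate early and dissociation stress genes 3 fell and 1 rose (4 and 2 adjusted over the list alone), with the small heat shock gene Hspb1 at -1.47 ± 0.15 (adjusted p = 0.00331). The list was called lower (camera adjusted p = 0.00622, adjusted p = 0.761 with an estimated correlation) except without control replicate 4 (0.0592). Extracellular matrix genes split, 2 rising and 2 falling of 32 (camera adjusted p = 0.238): Thbs1 fell by 2.16 ± 0.26 (0.00586). Among 15 Notch receptors, ligands and regulators 3 fell and 1 rose (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.224). Markers of other cell types gave no camera call: 3 of 8 pericyte and smooth muscle markers fell (adjusted p = 0.327), 2 of 5 fibro-adipogenic markers fell (0.199), 1 of 6 Schwann and glial markers fell (Ngfr, -2.97 ± 0.27, adjusted p = 0.00253, list 0.0570), and 1 of 4 endothelial markers rose (0.843). Quiescence genes (1 up and 1 down of 14; 0.545), glycolysis genes (1 of 20 up; 0.769) and pluripotency genes (1 of 3 up; 0.141) gave none either. In the remaining 10 lists no member passed limma's test; of their 159 members 25 were past an unadjusted p of 0.05 and 0 passed with limma-voom. Of these lists cell cycle genes were called higher as a group (30 measured, camera adjusted p = 0.00126, adjusted p = 0.761 with an estimated correlation).

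In all, 1325 of 12314 tested genes differed between cultured N1OE and control, 583 higher and 742 lower. Which direction held more genes depended on the processing: median ratio scaling gave 433 higher and 849 lower, a pseudocount of 5 CPM 588 and 530, and limma-voom 522 and 434. The count was 354, 164 and 158 without N1OE replicate 1, 2 and 3, and 584 without control replicate 2. Control replicate 1 and N1OE replicate 1 have another form of description than the other 5 libraries. Without both, 196 genes passed (41 higher, 155 lower, 195 of them shared), 2 of 9 Notch target genes rose (camera adjusted p = 0.00760), and the list of myogenic regulators was lower (1.7e-06). No direction turned, but 11 lists were called in place of 6.

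**Figure D3:**
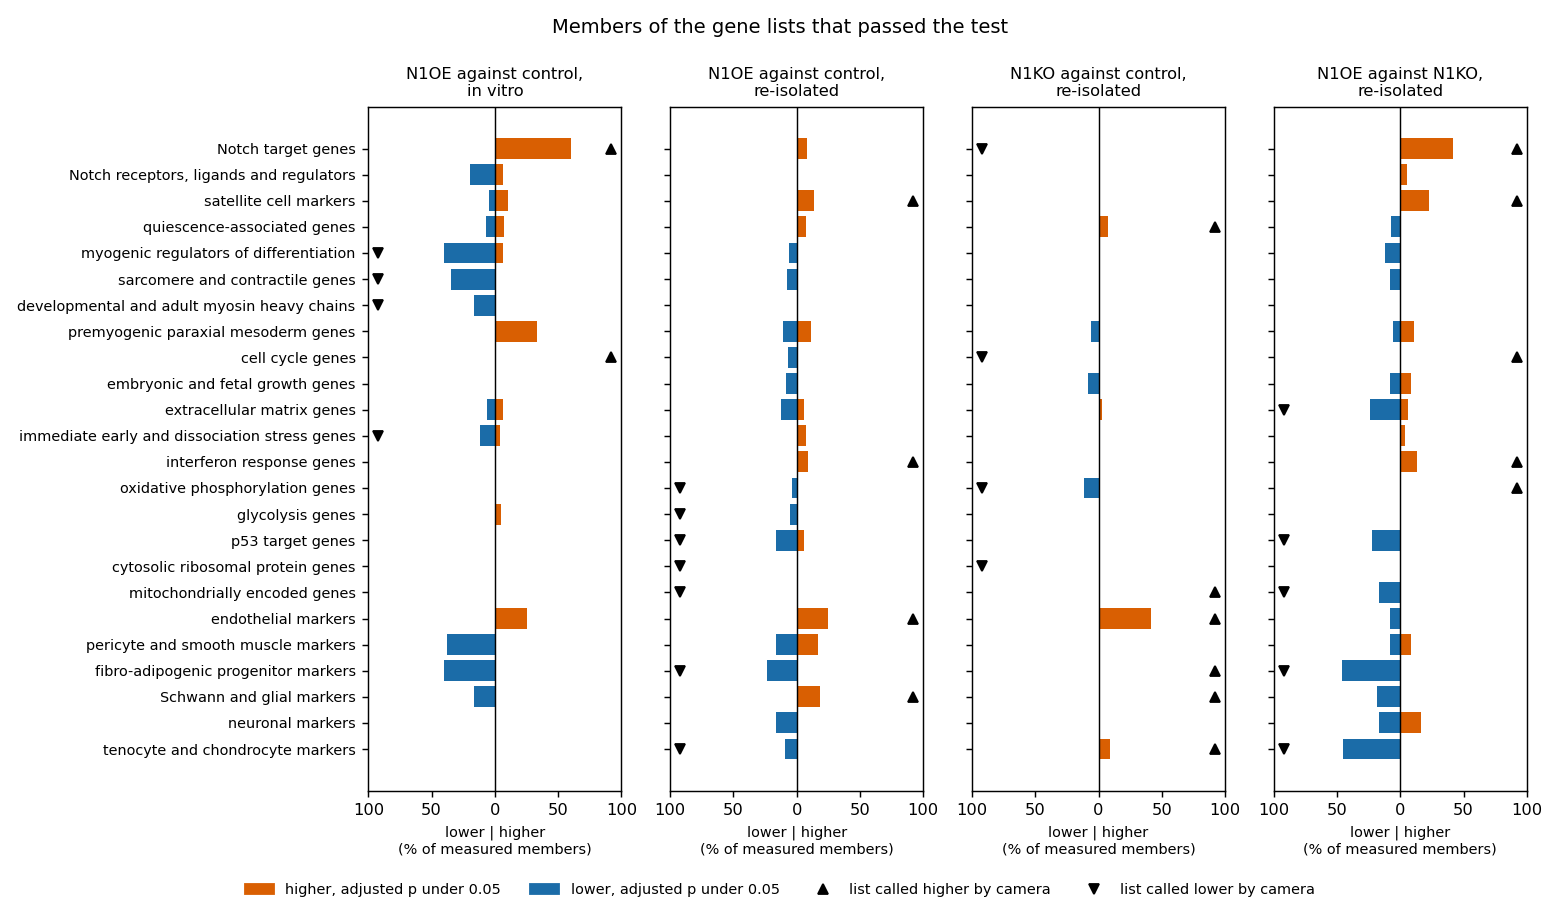
Share of the measured members of each gene list that were higher (orange, to the right) or lower (blue, to the left) with an adjusted p under 0.05, in 4 comparisons; triangles mark lists called by camera with a preset correlation. In culture 6 of 10 Notch target genes rose with N1OE, and 5 of 12 endothelial markers rose in N1KO.

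The next comparison asked how re-isolated satellite cells with NICD1 differ from control ones. Over all 9 controls 1000 of 14155 tested genes differed, 535 higher and 465 lower in N1OE. The split depended on the processing: median ratio scaling gave 493 higher and 535 lower, a pseudocount of 5 CPM 766 and 354, and limma-voom 651 and 263. Against the 5 marked controls 1630 differed (898 higher, 732 lower; 773 shared with the pooled calls), and against the 4 unmarked controls 2731 (1324 higher, 1407 lower; 798 shared). All 993 and 972 pooled calls tested within the sets kept direction, which shared libraries favour. These sets follow the headers and were chosen after the data were seen. With the sets planned from the descriptions, which place control replicate 7 with the unmarked, the counts were 1326 (marked) and 889 (unmarked) (671 and 622 shared), so the unmarked count rests on the place of 1 library. Without N1OE replicate 2 or 3, 562 and 593 genes passed.

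By the naming rule the steepest rises exceed all controls of both sets. Vat1l (chromosome 8, 114205612 to 114374071) stood at 134 ± 95.9 CPM in N1OE and 0.199 ± 0.536 in controls (log2 fold change 10.12 ± 0.77, adjusted p = 2.97e-07; 10.40 against marked and 9.77 against unmarked controls). The homeobox gene Otx2 (chromosome 14, 48657677 to 48673819) was higher by 8.07 ± 0.95 (8.75 and 7.22), the anion transporter gene Slc26a8 by 7.93 ± 0.73 (8.54 and 7.16), Zic4, a zinc finger transcription factor gene, by 7.84 ± 1.18 (10.29 and 4.77). The iron oxidase gene Heph was higher by 7.80 ± 0.91 (8.67 and 6.71), the Wnt agonist gene Rspo1 by 7.40 ± 1.29 (10.03 and 4.11), the GABA-synthesising enzyme gene Gad1 by 7.39 ± 0.82 (8.46 and 6.04) and Crtac1 by 7.38 ± 0.89 (7.62 and 7.07). The prostacyclin synthase gene Ptgis fell by 6.83 ± 0.91 (adjusted p = 9.97e-05; -8.12 and -5.22), Xpnpep2 by 5.44 ± 0.76, Clec11a by 5.08 ± 0.56. The mesothelin gene Msln fell by 4.70 ± 0.63, the retinoic acid binding gene Crabp2 by 4.64 ± 0.49 and Ly6a, which encodes the surface antigen Sca-1, by 4.30 ± 0.56. All were lower within both sets, by the same rule. Tmem26 fell by 5.02 ± 1.01 (-6.61 against marked controls; too low to test against unmarked ones). Krt19 measured 0.00857 CPM in N1OE and 10.6 in controls (read ratio 890, interval 160 to 35180, adjusted p = 0.0202); it missed the threshold without N1OE replicate 2, 3 or 4 (0.0649, 0.0625 and 0.0602). Its read ratio was 538 without control replicate 9 and at least 178 without N1OE replicate 1, which holds its read.

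Among the Notch targets Dtx4 (chromosome 19, 12466338 to 12501454) rose by 1.55 ± 0.43 (adjusted p = 0.0326; 179 ± 22.8 against 70.5 ± 40.8 CPM; 1.5 within the marked set and 1.61 within the unmarked), and the other 11 of 12 did not pass. The call was lost without control replicate 9 (0.0514) or N1OE replicate 1, 2, 3 or 4 (0.0603, 0.105, 0.0889 and 0.0711). The list was not called (camera adjusted p = 0.0663), but it was against the marked controls, where 5 members rose (5.27e-05): Hey1 by 2.07, Heyl by 2.29, Hes5 by 3.75 and Nrarp by 2.73, with Dtx4. Against the unmarked controls 2 rose and 2 fell (camera adjusted p = 0.619), and Nrarp fell by 2.05 (adjusted p = 0.000299). Notch1 was 1.22 ± 0.55 higher over all controls, which did not pass (adjusted p = 0.189; 2.04, adjusted p = 0.00383 against marked and 0.19, adjusted p = 0.742 against unmarked controls). In the list of Notch receptors, ligands and regulators none of 18 passed limma's test (4 at an unadjusted p under 0.05 and 0 with limma-voom, camera adjusted p = 0.0888).

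Satellite cell markers rose: 3 of 22, none falling (6 adjusted over the list alone, camera adjusted p = 0.00699, adjusted p = 0.529 with an estimated correlation). They were Megf10, an engulfment receptor gene of satellite cells (1.40 ± 0.33, 0.0122), Chrdl2 (4.19 ± 1.02, 0.0158) and the growth factor antagonist Spry1 (1.15 ± 0.31, 0.0297). Within the sets 7 rose against the marked controls (0.00121), and 5 rose and 2 fell against the unmarked ones (0.0912). Megf10 was lost without N1OE replicate 2 (0.0577) or 3 (0.0648), Chrdl2 without N1OE replicate 2 (0.0650), and Spry1 without N1OE replicate 2 (0.135), 3 (0.0536) or 4 (0.0606) or control replicate 9 (0.0510). Premyogenic genes split, 2 rising and 2 falling of 18 (camera adjusted p = 0.698): Pax3, the induced factor, was 2.27 ± 0.52 higher (adjusted p = 0.0105; 2.98 and 1.39 within the marked and unmarked sets), Msc 1.90 ± 0.41 higher (0.00678), and the homeobox gene Meox2 fell by 2.50 ± 0.54 (0.00678). Of 25 sarcomere and contractile genes 2 fell (camera adjusted p = 0.0777), Tpm2 by 2.19 ± 0.39 (0.00145). Yet the list was higher against marked controls (5 up, 2 down; 0.0469) and lower against unmarked ones (0 up, 15 down; 5.42e-12). Myogenic regulators went from 1 of 16 lower (0.0709) to 2 up and 1 down against marked (0.940) and 1 up and 7 down against unmarked controls (0.000156). Cell cycle genes, 2 of 30 lower (0.266), were lower against marked (5.27e-05) and higher against unmarked controls (0.0481).

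Several metabolic and stress groups were lower in N1OE. Cytosolic ribosomal protein genes fell as a list of 32 (camera adjusted p = 1.36e-06, adjusted p = 0.529 with an estimated correlation) with no member passing limma's test (14 at an unadjusted p under 0.05, 0 with limma-voom), and did so within both sets (0.00374 and 3.88e-08). The mitochondrially encoded list was lower too (0 of 12 members passed, 5 at an unadjusted p under 0.05, 0 with limma-voom; 0.00362, adjusted p = 0.571 with an estimated correlation), but against marked controls alone it was not (0.344). Glycolysis genes fell (1 of 20: the muscle enolase Eno3, -2.58 ± 0.36, adjusted p = 0.000145, list 0.00896, adjusted p = 0.574 with an estimated correlation), not against marked controls (0.911) and not without N1OE replicate 2 (0.0662). Oxidative phosphorylation genes (1 of 26 lower; 0.00896, adjusted p = 0.529 with an estimated correlation) were not called against unmarked controls (0.0777). Of 18 p53 targets 3 fell and 1 rose (0.0148, adjusted p = 0.205 with an estimated correlation, unmarked controls 0.190): the stress gene Sesn2 fell by 1.74 ± 0.32 (0.00182), and the apoptosis gene Pmaip1 was 1.96 ± 0.37 higher (0.00278). Interferon response genes rose (2 of 23; 0.00896, adjusted p = 0.571 with an estimated correlation), though not against unmarked controls (0.406). Extracellular matrix genes had 2 up and 4 down of 33 (7 down and 4 up adjusted over the list alone; 0.161), 13 down against marked controls (2.2e-06); Col1a1, the collagen I gene, fell by 2.32 ± 0.53 (0.00982), which missed the threshold without N1OE replicate 4 (0.0546). Immediate early genes had 2 of 26 higher (0.0756; 0.000409 against marked controls).

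Markers of other cell types moved with the group. Of 12 endothelial markers 3 rose (7 adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.529 with an estimated correlation). The list was called within both sets (0.00062 and 0.0075). The VEGF receptor gene Kdr was 4.80 ± 0.92 higher (adjusted p = 0.00288; 11.7 against 0.908 CPM). Fibro-adipogenic markers fell (3 of 13; 0.00199, adjusted p = 0.529 with an estimated correlation, unmarked controls 0.406), with Clec3b at -3.09 ± 0.69 (0.00895). Tenocyte and chondrocyte markers fell (1 of 11, Fmod, -4.00 ± 0.94, 0.0127, list 0.0148, adjusted p = 0.363 with an estimated correlation, unmarked controls 0.267); Fmod missed the threshold without N1OE replicate 2 (0.0528) and the list without N1OE replicate 4 (0.0501). Macrophage markers fell (2 of 17; 0.0175, adjusted p = 0.583 with an estimated correlation, unmarked controls 0.809), except without control replicate 4 or 9 or N1OE replicate 4 (up to 0.157). Lymphocyte and neutrophil markers rose (2 of 4; 0.00699, adjusted p = 0.205 with an estimated correlation): the T cell gene Cd3e measured 3.06 CPM against 0.00582 (read ratio 534, interval 94.9 to 21180; at least 170 without control replicate 9, which holds the read) and the chemokine gene Ccl5 was 3.64 ± 0.66 higher (0.00189). Schwann and glial markers rose (2 of 11; 0.0107, adjusted p = 0.529 with an estimated correlation, unmarked controls 0.0506), among them Sox10 (3.13 ± 0.60, 0.00285). Pericyte and smooth muscle markers (2 up, 2 down of 12; 0.661), quiescence genes (1 of 14 up; 0.655), neuronal markers (1 of 6 down; 0.311), growth genes (1 of 12 down; 0.227) and myosin heavy chains (0 of 6 passed limma's test, 2 at an unadjusted p under 0.05, 0 with limma-voom; 0.331) gave no call.

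The third comparison asked what loss of Notch1 changes in re-isolated satellite cells. Over all 9 controls 93 of 14155 genes differed, 66 higher and 27 lower in N1KO. Against the unmarked controls, like N1KO in read ratio but not Ddx3y, 1013 differed (553 higher, 460 lower, 72 shared with the pooled calls). Whether they hold cells of the line was not tested. Against the marked controls 412 did (221 higher, 191 lower, 56 shared). All 89 and 90 pooled calls tested within the sets kept direction, which shared libraries favour. With control replicate 7 as unmarked, by its description, the counts were 14 (unmarked) and 31 (marked). Without N1KO replicate 2, 12 genes passed, all higher. Without N1KO replicate 1 it was 46 (20 higher, 26 lower) and without replicate 3 again 93 (43 higher, 50 lower), so the excess of higher genes was lost. Leaving out control replicate 2, 4, 5 or 7 gave 50, 50, 49 and 56, and N1OE replicate 1, 2 or 3 from the shared fit 48, 52 and 56.

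The largest rises in N1KO were in single genes. Ibsp (chromosome 5, 104299171 to 104311469), which encodes bone sialoprotein, measured 429 ± 615 CPM against 2.26 ± 6.56 (log2 fold change 9.86 ± 1.42, adjusted p = 0.00258; 10.10 against unmarked and 9.67 against marked controls). Vat1l was 8.67 ± 0.86 higher (2.92e-05; 8.32 and 8.95), Otx2 7.33 ± 1.06 (0.00258; 6.48 and 8.01) and the immunoglobulin family gene Igsf23 6.41 ± 0.96 (0.00335; 6.56 and 6.29). Each of these 4 passed in every fit that left out 1 library. The tachykinin gene Tac1 (6.96 ± 1.13, 0.00643) was lost without N1KO replicate 2 (0.122), Fmr1nb (6.73 ± 1.10, 0.00685) without N1KO replicate 1 (0.0679) or 2 (0.122), and Fam167a (6.46 ± 1.13, 0.0135) without N1KO replicate 1 (0.0591) or 2 (0.161). Falls were smaller: Pm20d1 by 1.98 ± 0.38 (0.0225), lost without N1KO replicate 1 (0.0916) or 2 (0.136). Calls near the threshold, among them the connexin gene Gjb1 (5.77 against 0.0192 CPM; read ratio 359, interval 122 to 1751; 0.0386), Hunk (-2.55 ± 0.56, 0.0386), Plagl1 (-2.52 ± 0.56, 0.0410), Atp5k (-2.27 ± 0.49, 0.0378), Nes (-2.15 ± 0.46, 0.0372) and Fdps (-2.08 ± 0.47, 0.0424), were each lost in at least 6 of the 16 fits that leave out 1 library, with adjusted p-values up to 0.298, 0.248, 0.289, 0.189, 0.367 and 0.2497.

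Of 12 Notch target genes 0 passed limma's test over all controls (3 at an unadjusted p under 0.05, all lower, and 0 with limma-voom; 2 lower adjusted over the list alone), and the list was called lower (camera adjusted p = 0.0057, adjusted p = 0.575 with an estimated correlation). Against the unmarked controls 6 fell (1.25e-05): Hes5 by 6.30 (adjusted p = 0.00592), Hey1 by 2.82 (0.00623), Heyl by 2.25 (0.0101), Nrarp by 3.78 (0.0221), Dtx1 by 4.17 (0.0282) and Hey2 by 3.08 (0.0293). Against the marked controls none did (camera adjusted p = 0.852). Notch1 was at -1.57 ± 0.61 over all controls (adjusted p = 0.286), at -2.60 (0.00623) against unmarked and at -0.75 (0.484) against marked ones. Myod1 did not pass over all controls (-1.91, 0.430), and fell by 3.70 (0.00709) against unmarked ones. Myogenic regulators followed (0 of 16 passed over all controls, 3 at an unadjusted p under 0.05, 0 with limma-voom, camera adjusted p = 0.0877, 0.684 against marked, 0.00211 and 3 down against unmarked). Sarcomere genes gave no pooled call (0 of 25, 0 at an unadjusted p under 0.05, 0 with limma-voom; 0.518) and opposite ones within the sets, lower against unmarked (7 down; 2.86e-08) and higher against marked controls (0.00538).

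Endothelial markers rose in N1KO, 5 of 12 with none falling (9 adjusted over the list alone, camera adjusted p = 2.79e-11, adjusted p = 0.0333 with an estimated correlation, 4.75e-05 against unmarked and 6.55e-08 against marked controls). They included the tight junction gene Cldn5 (4.79 ± 0.89, 0.0174) and the adhesion gene Pecam1 (2.79 ± 0.57, 0.0337); Kdr (4.44 ± 1.02, 0.0484), also among the 5, was chosen after its values were seen. Cldn5 was lost without N1KO replicate 2 (0.195) and Pecam1 without N1KO replicate 1, 2 or 3 (0.0529, 0.253 and 0.0740), and Kdr in 13 of the 16 fits that leave out 1 library (up to 0.246). Tenocyte and chondrocyte markers rose (1 of 11, 6 adjusted over the list alone; 4.44e-05, adjusted p = 0.0333 with an estimated correlation, 0.00026 and 0.000521 within the sets). Their members include Comp (3.84 ± 0.89, 0.0484), a cartilage matrix gene, lost in 14 of 16 such fits (up to 0.298). Tnmd (6.31 ± 1.52, 0.0575) did not pass. Fibro-adipogenic markers were called higher (2.06e-05, adjusted p = 0.283 with an estimated correlation, 3.48e-08 against unmarked, 0.105 against marked controls; 0 of 13 passed limma's test, 5 at an unadjusted p under 0.05, 1 with limma-voom, 2 adjusted over the list alone). Macrophage markers were higher as a list (0.000378, adjusted p = 0.590 with an estimated correlation), but not against marked controls (0.281) and not without N1KO replicate 1 (0.0503). So were Schwann and glial markers (0.000317, adjusted p = 0.283 with an estimated correlation, 0.0199 and 0.00747 within the sets). In these 2 lists 0 members passed limma's test, against 2 and 4 at an unadjusted p under 0.05 and 0 and 1 with limma-voom. Pericyte and smooth muscle markers were not (0.847), nor were neuronal (0.370) or lymphocyte markers (0.676).

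Oxidative phosphorylation genes fell, 3 of 26 with none rising (9 adjusted over the list alone, camera adjusted p = 1.94e-11, adjusted p = 0.0333 with an estimated correlation, 3.41e-06 against unmarked and 2.83e-07 against marked controls). The listed complex I gene Ndufa1 fell by 2.0 ± 0.40 (adjusted p = 0.0267), lost without N1KO replicate 2 or 3 (0.127 each). Outside the list the complex III gene Uqcrq fell by 2.0 ± 0.34 (0.00931), lost likewise (0.121 and 0.0503). Cell cycle genes were lower as a list (0 of 30 passed limma's test, 10 at an unadjusted p under 0.05, 0 with limma-voom; 2.25e-08, adjusted p = 0.478 with an estimated correlation), against marked (7.7e-08) but not unmarked controls (0.281). Ribosomal protein genes were lower (0.000265, adjusted p = 0.678 with an estimated correlation) against unmarked (3.41e-06) but not marked controls (0.684). The mitochondrially encoded list was higher (0.0468, adjusted p = 0.716 with an estimated correlation) against marked (3.22e-05) but not unmarked controls (0.281), and was lost without control replicate 4, 7 or 8, N1OE replicate 2 or 3 or N1KO replicate 2 or 3 (up to 0.243). Quiescence genes were higher (1 of 14, the transcription factor Klf2, 2.13 ± 0.47, 0.0386, list 0.0187, adjusted p = 0.283 with an estimated correlation, unmarked controls 0.336; 0.0503 without N1KO replicate 2), Klf2 being lost in 8 such fits (up to 0.367). Of 33 extracellular matrix genes 1 rose (6 adjusted over the list alone; 0.0877; 2.75e-07 with 11 up against unmarked controls), the collagen I gene Col1a2 (5.47 ± 1.16, 0.0356; 7099 ± 4270 against 349 ± 358 CPM), lost without N1KO replicate 1 (0.127) or 2 (0.246) or any N1OE library (0.0502 to 0.0533).

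**Figure D4:**
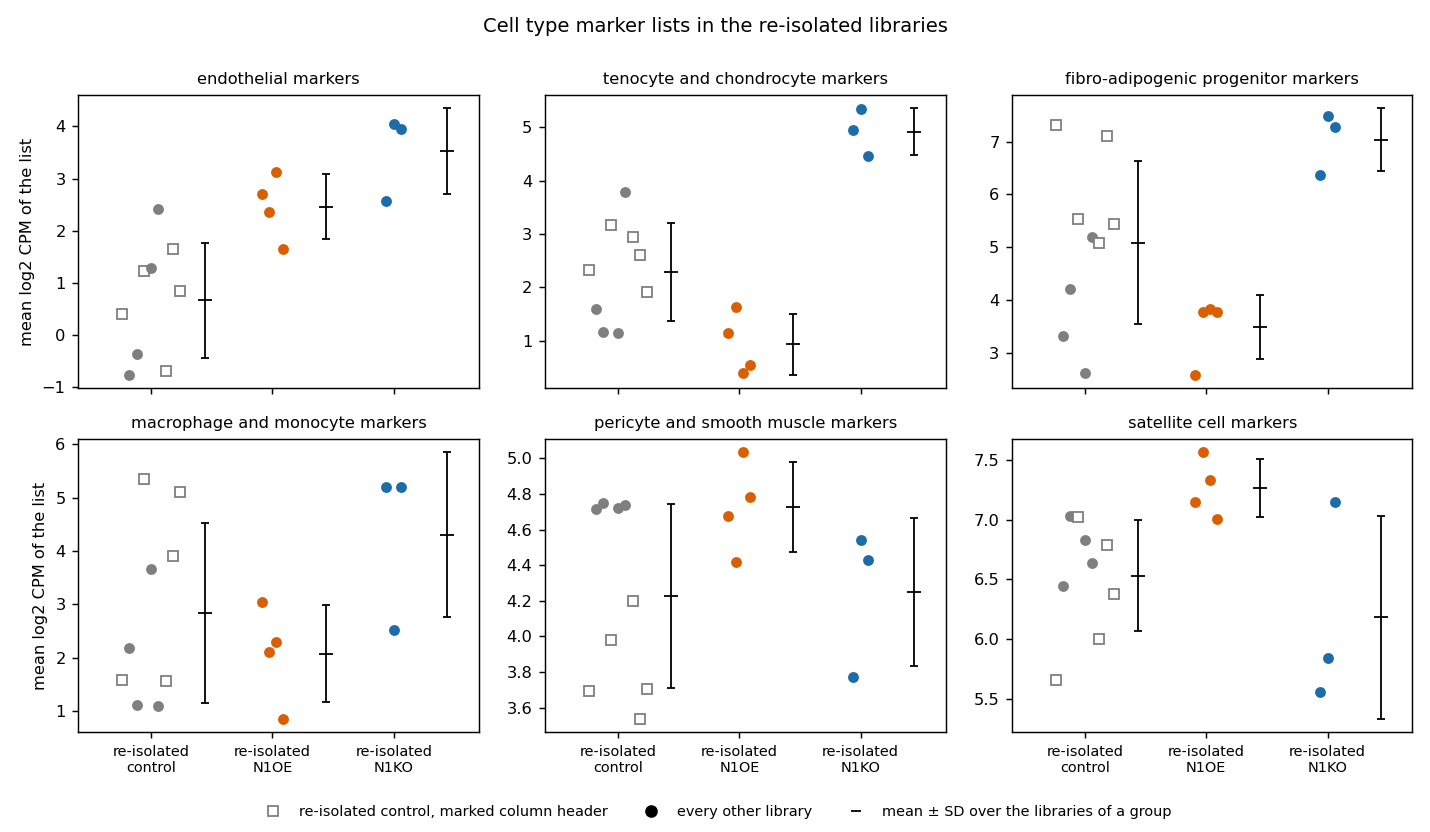
Mean log2 CPM of 6 marker lists in each re-isolated library, with the mean and SD of each group. The 3 N1KO libraries lie above all 4 unmarked controls for endothelial, tenocyte and fibro-adipogenic markers and below all 4 for pericyte markers.

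The fourth comparison set re-isolated N1OE against N1KO. By the read ratio these groups lie in different library sets, so such a set and the group cannot be told apart here. Of 14155 genes 1040 differed, 413 higher and 627 lower in N1OE; without N1KO replicate 1 or 2 the counts were 465 and 489. The excess of lower genes was absent without N1KO replicate 3 (470 higher, 449 lower) and with array weights (1040 higher, 1027 lower). Notch1 was 2.79 ± 0.70 higher in N1OE (adjusted p = 0.0177; 188 ± 76.8 against 29.3 ± 20.2 CPM), lost without N1KO replicate 1 (0.110) or 2 (0.0828) or N1OE replicate 2 (0.0560). Of 12 Notch target genes 5 rose and none fell (7 adjusted over the list alone, camera adjusted p = 0.00213, adjusted p = 0.603 with an estimated correlation). Hey2 was 3.04 ± 0.68 higher (0.00847; 0.0777 without N1KO replicate 1) and Dtx4 2.17 ± 0.54 (0.0181; 0.152 and 0.0664 without N1KO replicate 1 and 2). Hes5 measured 5.21 against 0.0537 CPM (read ratio 87.9, interval 29.9 to 428, adjusted p = 0.0185). Satellite cell markers rose as well (5 of 22, 9 adjusted over the list alone; 0.00213, adjusted p = 0.603 with an estimated correlation), among them Megf10 (1.94 ± 0.42, 0.00629). The receptor gene Met, from the premyogenic list, was 2.45 ± 0.42 higher (0.00139). Hes5 was lost without N1KO replicate 1 or 2 or N1OE replicate 2 (0.0853, 0.0800 and 0.0567).

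Tenocyte and fibro-adipogenic markers were lower in N1OE than in N1KO. Ibsp had no read in N1OE and 1137, 111 and 37.6 CPM in the 3 N1KO libraries, at least 11350-fold lower on their mean of 429. That limit rests on N1KO replicate 1: it is 1967-fold without it (7188 without N1OE replicate 1). The tendon gene Tnmd was at -10.41 ± 1.74, Lrrc15 at -9.48 ± 1.79, Moxd1 at -8.87 ± 1.80, the Wnt modulator Sfrp2 at -8.81 ± 1.29 (1.61 against 675 CPM) and the collagenase gene Mmp13 at -9.31 ± 2.06. Epyc measured 0.0559 against 82.6 CPM (read ratio 2196, interval 751 to 10650) and the pepsinogen gene Pgc 0.0215 against 512 (40300, 7233 to 1592000). Mmp13 was lost without N1KO replicate 1 (0.0624) or 2 (0.0686) and Pgc without N1KO replicate 1 (0.109) or 3 (0.0591). The read ratio of Pgc was 18370 without N1KO replicate 1, 25520 without N1OE replicate 1 and at least 11560 without N1OE replicate 3, and that of Epyc 1391 and 5624 without N1OE replicate 1 and 3. Of 11 tenocyte and chondrocyte markers 5 fell (8 adjusted over the list alone, camera adjusted p = 1.88e-05, adjusted p = 0.0379 with an estimated correlation), such as Fmod (-6.29 ± 1.19) and Comp (-5.46 ± 1.02). Of 13 fibro-adipogenic markers 6 fell (10 adjusted over the list alone; 1.5e-07, adjusted p = 0.238 with an estimated correlation), with Ly6a at -5.48 ± 0.71 (0.000107). Extracellular matrix genes had 8 down and 2 up of 33 (0.0453, adjusted p = 0.766 with an estimated correlation, lost without control replicate 4, N1OE replicate 2 or 4 or N1KO replicate 2, up to 0.159): Col1a2 fell by 8.36 ± 1.33 (0.000688), Postn by 4.19 ± 0.72 and Col1a1 by 3.88 ± 0.67.

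In the other direction Slc38a5, an amino acid transporter gene, had no read in N1KO and was at least 395-fold higher in N1OE (21.7 ± 7.55 CPM), and the synaptotagmin family gene Syt14 at least 95-fold higher. Heph was 7.70 ± 1.16 higher, Calhm1 6.88 ± 1.31 and Gprin2 6.74 ± 1.20. Gad1 measured 23.3 against 0.0179 CPM (read ratio 1376, interval 247 to 54360), Clec4g 15.0 against 0.0179 (725, 130 to 28670) and Spag6 14.7 against 0.0537 (285, 97.4 to 1385). Without N1KO replicate 3 the limits were 260 for Slc38a5 and 62.6 for Syt14, and at least 280 for Gad1, 180 for Clec4g and 176 for Spag6, whose N1KO reads that library holds. Clec4g had a ratio of 374 without N1OE replicate 4. Of 18 p53 targets 4 fell (camera adjusted p = 0.00213, adjusted p = 0.0460 with an estimated correlation), Sesn2 by 2.0 ± 0.40 (0.0042). Mitochondrially encoded genes fell (2 of 12, 5 adjusted over the list alone; 0.000276, adjusted p = 0.603 with an estimated correlation) and so did macrophage markers (2 of 17; 6.06e-05, adjusted p = 0.603 with an estimated correlation), Cd14 by 2.97 ± 0.63 (0.00569). Interferon response genes rose (3 of 23; 0.0238, adjusted p = 0.679 with an estimated correlation, 0.0626 without N1OE replicate 4). Oxidative phosphorylation genes were higher as a list (0 of 26 passed limma's test, 5 at an unadjusted p under 0.05, 0 with limma-voom; 0.0254, adjusted p = 0.649 with an estimated correlation), as were cell cycle genes (0 of 30, 7 at an unadjusted p under 0.05, 0 with limma-voom; 0.0115, adjusted p = 0.803 with an estimated correlation). The first was lost without N1OE replicate 1 or 4 or N1KO replicate 3 (up to 0.321) and the second without N1OE replicate 1 or 4 or N1KO replicate 2 (up to 0.599). Sarcomere genes (2 of 25 down; 0.456), endothelial markers (1 of 12 down; 0.0735) and immediate early genes (1 of 26 up; 0.911) gave no call.

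The fifth comparison set re-isolated control satellite cells against the cultured control progenitors; RNA extraction and library kit changed with the setting, so the setting and the kit cannot be told apart. Of 13731 tested genes 7974 differed, 3316 higher and 4658 lower after re-isolation (8287 with the marked and 8678 with the unmarked controls only, 7112 and 7047 of them shared), with a median of all genes at -0.23. Median ratio scaling moves that median to 0.02 and gives 4023 higher and 3927 lower, without an excess of lower genes. Pax7 (chromosome 4, 139737062 to 139833528), the transcription factor of satellite cells, rose from 0.0561 ± 0.0844 to 56.1 ± 32.1 CPM (9.0 ± 0.56, adjusted p = 1.03e-08). Of 21 satellite cell markers 9 rose and 3 fell (camera adjusted p = 0.0354, adjusted p = 0.436 with an estimated correlation, 0.0668 with the marked controls only, 0.0558 without cultured control replicate 3), including Vcam1 (2.73 ± 0.31), Itga7 (3.85 ± 0.50) and Cd34 (6.58 ± 0.90). Of 12 Notch target genes 8 rose and 2 fell (0.00742, adjusted p = 0.436 with an estimated correlation): Hey1 was 4.41 ± 0.68 higher, Heyl 4.63 ± 0.76 and Gadd45g 4.86 ± 0.34, while Notch3 fell by 2.16 ± 0.48 and Lfng by 2.59 ± 0.47. Notch1 did not differ past the threshold (-0.04 ± 0.56, 0.951), but was 0.99 higher with the unmarked controls only (0.00109). Myh3 fell by 5.47 ± 0.81 and the adult fast chain Myh1 was 3.56 ± 0.74 higher, the 2 of 6 myosin heavy chains that changed (0.953).

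Proliferation and growth genes fell. Of 30 cell cycle genes 20 fell and none rose (23 adjusted over the list alone; 0.00173, adjusted p = 0.574 with an estimated correlation), Mki67 by 4.04 ± 0.73 and Top2a by 2.96 ± 0.44. Of 14 embryonic and fetal growth genes 10 fell and 3 rose (0.0331, adjusted p = 0.344 with an estimated correlation), Lin28b by 6.20 ± 0.78 and Trim71 by 6.41 ± 0.58. Cytosolic ribosomal protein genes fell (26 of 32; 1.08e-06, adjusted p = 0.436 with an estimated correlation), Rps24 by 3.33 ± 0.34. Immediate early genes rose (24 of 26; 1.07e-15, adjusted p = 0.344 with an estimated correlation), Fos by 8.64 ± 0.50 and Dusp1 by 7.80 ± 0.38, and interferon response genes (20 up, 1 down of 23; 7.45e-10, adjusted p = 0.344 with an estimated correlation), Ifit1 by 7.65 ± 0.56. Extracellular matrix genes had 17 up and 6 down of 33 (0.00486, adjusted p = 0.552 with an estimated correlation, 0.379 with the unmarked controls only), Bgn 8.65 ± 0.68 higher and Col4a1 2.35 ± 0.25 lower (log2 fold change -2.35). Glycolysis genes had 11 up and 1 down of 20 (0.0186, adjusted p = 0.581 with an estimated correlation, 0.245 with the marked controls only). Markers of other cell types rose: macrophage (15 of 17; 4.39e-07, adjusted p = 0.371 with an estimated correlation), with C1qb at least 887-fold higher and C1qa at least 371-fold. So did pericyte (9 of 12, 1 falling; 0.00142, adjusted p = 0.344 with an estimated correlation), fibro-adipogenic (9 of 13; 0.00251, adjusted p = 0.436 with an estimated correlation), with Pi16 8.28 ± 0.73 higher, and Schwann markers (6 of 11, 1 falling; 0.0156, adjusted p = 0.436 with an estimated correlation). Endothelial markers had 4 of 11 up (0.0615) and tenocyte markers 5 up and 1 down of 10 (0.105). In the lymphocyte, pluripotency and erythroid lists, with too few measured genes for camera, 1 member each rose. The steepest single changes were Prelp (13.43 ± 0.69), Fmod (11.46 ± 1.11), Dpt (11.32 ± 0.61), Bdkrb1 (11.32 ± 0.55), Fgl2 (10.62 ± 0.53), Hspa1a (10.46 ± 0.51) and Has1 (10.18 ± 0.59). Msx1 stood at 110 against 0.0265 CPM. On the falling side stood Vat1l (-8.89 ± 0.88), Syndig1 (-8.57 ± 0.59), Svop (-8.17 ± 0.85), Ogdhl (-8.09 ± 0.65), Hmga2 (-8.08 ± 1.12), Scg2 (-8.07 ± 0.98), Kcnd2 (at least 1384-fold lower, 768 without cultured control replicate 2) and Hand1 (0.00384 against 43.9 CPM).

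The last comparison tested whether the N1OE effect differed between the settings, as the effect in re-isolated cells minus the effect in culture. It did so for 475 of 14509 genes, 343 with a higher and 132 with a lower effect after re-isolation (967 with the marked and 1546 with the unmarked controls only, 443 and 445 of them shared; 240 and 262 without cultured N1OE replicate 3 and 2). Of 15 lists called, 8 had higher and 7 lower effects after re-isolation. Of 25 sarcomere genes 6 had a higher effect after re-isolation (13 adjusted over the list alone, camera adjusted p = 3.34e-08, adjusted p = 0.394 with an estimated correlation, 1.34e-13 and 0.0142 with the marked and unmarked controls only), and Myl1 differed by 4.76 ± 1.01 (0.0075). Of 16 myogenic regulators 2 did (5 adjusted over the list alone; 0.00145, adjusted p = 0.394 with an estimated correlation, 0.176 with the unmarked controls only), the differentiation factor Myog by 4.37 ± 0.84 (0.00327). Heyl differed by -4.01 ± 1.02 (0.0271) and Hey1 by -3.58 ± 0.93 (0.0304), 2 of 12 Notch target genes with a lower effect after re-isolation (3 lower and 1 higher adjusted over the list alone; 0.0101, adjusted p = 0.394 with an estimated correlation, 0.178 with the marked controls only). Both were lost without cultured control replicate 2 (Heyl 0.0742, Hey1 0.0814) or 3 (0.0660 and 0.0611), cultured N1OE replicate 1 (0.0920 and 0.0926), 2 (0.0567 and 0.0701) or 3 (0.0639 and 0.0739) or re-isolated N1OE replicate 3 (0.0511 and 0.0632), Heyl also without re-isolated N1OE replicate 4 (0.0539) and Hey1 without replicate 1 (0.0594). Schwann and glial markers (2 of 11 higher; 0.000551, adjusted p = 0.311 with an estimated correlation), with Ngfr at 4.01 ± 0.80, and immediate early genes (1 of 26 higher; 0.00038, adjusted p = 0.394 with an estimated correlation, 0.176 with the unmarked controls only), with Ccn2 at 3.98 ± 0.82, had higher effects as well.

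Among the other lists called for this difference, 8 had no member past limma's test and none with limma-voom. Myosin heavy chains had a higher effect after re-isolation (5 of 6 at an unadjusted p under 0.05 and 5 adjusted over the list alone, camera adjusted p = 0.000551, adjusted p = 0.311 with an estimated correlation). Interferon response genes did too (7 of 23 unadjusted, 0.00324, adjusted p = 0.398 with an estimated correlation, 0.138 with the unmarked controls only). Cell cycle genes had a lower effect (6 of 30 unadjusted, 6.37e-05, adjusted p = 0.437 with an estimated correlation, 0.176 with the unmarked controls only). So had cytosolic ribosomal protein genes (5 of 32, 1.88e-06, adjusted p = 0.394 with an estimated correlation) and oxidative phosphorylation genes (5 of 26, 0.000551, adjusted p = 0.364 with an estimated correlation). Glycolysis genes were lower (2 of 20, 0.0126, adjusted p = 0.504 with an estimated correlation), but not with the marked controls only (0.776) or without re-isolated N1OE replicate 2 (0.0762). Mitochondrially encoded genes were lower (1 of 12, 0.00528, adjusted p = 0.452 with an estimated correlation), but not with the marked controls only (0.275) or without re-isolated N1OE replicate 1 (0.0589). Tenocyte and chondrocyte markers were lower (2 of 12, 0.00611, adjusted p = 0.191 with an estimated correlation, 0.0936 with the unmarked controls only). Lymphocyte and neutrophil markers had a higher effect in 1 of 4, Cd3e (2 adjusted over the list alone, 0.00324, adjusted p = 0.168 with an estimated correlation, 0.0689 with the unmarked controls only). Endothelial markers, 1 higher and 1 lower of 12, were called higher (3 higher and 1 lower adjusted over the list alone, 0.0234, adjusted p = 0.394 with an estimated correlation, 0.0653 with the unmarked controls only). That call was lost without cultured control replicate 4, cultured N1OE replicate 2 or re-isolated N1OE replicate 1 or 3 (up to 0.0668).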

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

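The tests of separate library sets and of a preparation shared with N1KO, the test of a lower share of myogenic cells and the test of the choice of controls were chosen after the result was seen.

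A single library lay far from the rest of its group in 9 of 129 groups of values, 43 measures in each of 3 groups of 4 to 9 libraries (cultured controls, re-isolated controls and re-isolated N1OE). Chance alone marks about 1 in 20 groups. Re-isolated N1OE replicate 1 had the highest mean of cytosolic ribosomal protein genes (8.11 in log2 CPM) and the lowest mean of fibro-adipogenic markers (2.58), and was the library of its group with Dtx1, a Notch target, above 0 reads (0.0697 in log2 CPM). Re-isolated N1OE replicate 3 had the highest sarcomere mean (6.35). Among re-isolated controls, replicate 7 had the lowest Schwann and glial mean (1.05) and replicate 2 the highest share of mitochondrial reads (2.03 percent). Among cultured controls, replicate 1 had the highest premyogenic mean (2.50 in log2 CPM) and the highest share of mitochondrial reads (3.86 percent), and replicate 4 the highest mean of neuronal markers (2.88). No explanation of these was tested.

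The effect of N1OE differed between re-isolated and cultured cells by a test of the difference itself in 475 genes. Effects were higher after re-isolation for Vat1l (11.30 in log2), Slc1a3 (9.78), Crtac1 (9.65), Slc38a5 (8.97), Pla2g4e (8.53), Ermap (8.32), Lgi1 (8.27), Gimap9 (8.16), Cd3e (6.20) and Kdr (5.60). The contractile genes Mybpc1 (5.28), Myl1 (4.76), Acta1 (4.61) and Tnnt2 (4.08) followed, with Myog (4.37), Rbm24 (2.04), Ngfr (4.01), Erbb3 (2.60) and Ccn2 (3.98). Effects were lower after re-isolation for Sfrp2 (-8.66), Lgr5 (-7.29), Syt13 (-7.26), Trpv1 (-7.20), Dbx1 (-7.15), Stra6 (-7.04), Adh7 (-6.72), Flt1 (-6.47), Heyl (-4.01) and Hey1 (-3.58). Where a group holds 0 to 3 reads of a gene, as for Slc1a3 in cultured N1OE, the size depends on the prior count. Of 29 named genes called, 11 lost the call when 1 library was left out: 7, 10 and 11 of them without cultured N1OE replicate 1, 2 and 3, 3 to 7 without a cultured control, 3 to 7 without a re-isolated N1OE library and 1 each without re-isolated control replicate 4 or 9. They were Pla2g4e (adjusted p up to 0.113), Syt13 (0.0910), Trpv1 (0.0736), Tnnt2 (0.123), Rbm24 (0.1004), Kdr (0.0991), Erbb3 (0.0882), Acta1 (0.0863), Mybpc1 (0.0560), Heyl (0.0920) and Hey1 (0.0926). With limma-voom 15 lost it: all of these but Erbb3 and Acta1, with Ccn2 (0.312), Dbx1 (0.227), Slc1a3 (0.126), Lgi1 (0.121), Sfrp2 (0.105) and Ngfr (0.0524). RNA extraction and library kit changed with the setting, so a difference between settings and one between kits cannot be told apart.

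The first pattern weighed is that Y-linked transcripts lie near 0 in the 4 unmarked re-isolated controls. Eif2s3y averaged 0.92 ± 1.52 CPM there and 59.3 ± 14.6 in the marked controls. To test for a count adjustment that emptied genes in these 4 libraries, genes outside the Y chromosome were counted. Of them 0 had 20 CPM or more in each marked control and under 1 CPM in each of the 4. This cannot decide it, since Ddx3y and Eif2s3y themselves reached 2.77 and 3.19 CPM in the 4. Nor does it reach an adjustment that empties no gene. In re-isolated control replicate 1, 461, 78, 125 and 128 genes had 1, 2, 3 and 4 reads, which was not explained. The ratio of genes with 1 read to genes with 2 reads parts the 4 libraries and N1KO from the other re-isolated libraries by a gap of 2.67, but it does not decide whether a separate set of libraries is the source. As the source of the low Y-linked reads, a library preparation shared with N1KO is argued against. Ddx3y was above the highest of the 4 in 3 of 3 N1KO libraries (26.9 to 77.2 CPM against at most 2.77). The cultured libraries of the line all hold Y-linked reads, with Ddx3y at 34.0 to 73.0 CPM in controls and 32.5 to 34.8 in N1OE and Eif2s3y at 24.0 to 54.5 and 25.1 to 26.1. Whether the 4 libraries hold cells of this line, as their labels say, was not tested. A count adjustment and another difference peculiar to the 4 libraries stay open, and so do cells of female origin. The last were named beforehand but not tested, because the transcript that test needs is not in the deposited table.

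The next pattern is that transcripts of other cell types are higher in N1KO. To test a lower share of myogenic cells, the tenocyte mean minus the pericyte mean was set against the unmarked controls. It rose by more than 2 SD of these controls in 3 of 3 N1KO libraries (3.99, 3.61 and 2.85 in log2, SD 1.26). This does not decide it, because a lower share raises the markers of whichever other cells are present. Acta2, on the pericyte list, was also read in the cultured controls (414 CPM on average), so that list may not be free of myogenic cells. Satellite cell markers lay below all unmarked controls in 2 of 3 N1KO libraries and above all in 1. The choice of control libraries does not account for the endothelial rise, as the list was called against 2 of 2 sets. A single N1KO library is argued against too, since the call held without each of the 3 in turn (adjusted p = 5.13e-13, 6.09e-09 and 4.49e-09). A lower share of myogenic cells stays open. A mixture with particular cell types and a change in the cells themselves stay open as untested hypotheses.

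The last pattern is 8 genes whose lowest level in the 7 re-isolated N1OE and N1KO libraries lies above the highest of the 9 controls, with a mean of at least 5 CPM over the 7 and under 1 CPM over the 9. With the groups exchanged there were 0 such genes, counted without a test. A chance split was not decided, as this grouping was chosen after the result was seen. Of 100 splits of the 16 libraries only the real one gave as many such genes (highest other 1). Whether a separate set of libraries contributes was not decided: 4 of the 8 were called within both sets, but the choice of these genes already parts the groups within each set. The design itself sets N1OE and N1KO apart by engineering, and that explanation was not tested.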

How the results depend on the processing

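The header-based control sets and the other added alternatives named above were chosen after the data were seen. The planned edgeR and DESeq2 fits were not run. The deposited unit is log2 CPM, and limma-voom was the only count-based fit run on the recovered reads. Where no reason is given below, the cause was not tested.

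For cultured N1OE against control (1325 genes), array weights gave 3613, and leaving out the 2 libraries of the other description form gave 196, with fewer samples. Without each library in turn the count ran from 158 (N1OE replicate 3) to 1765 (control replicate 4). For re-isolated N1OE against control (1000), marked controls alone gave 1630 and unmarked ones 2731 by header, and 1326 and 889 by description. Left-out libraries gave 562 (N1OE replicate 2) to 1090 (control replicate 4).

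For N1KO against control (93), pseudocounts of 0.25, 1 and 5 CPM gave 177, 240 and 321, no filter 179, a mean of at least 5 CPM 57, array weights 492 and limma-voom 285. Unmarked controls by header gave 1013 and marked ones 412. By description they gave 14 and 31, and a fit of 2 groups alone 35. Left-out libraries gave 12 (N1KO replicate 2) to 108 (control replicate 1).

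For N1OE against N1KO (1040), array weights gave 2067 and a fit of 2 groups alone 1608, with left-out libraries from 465 (N1KO replicate 1) to 1231 (control replicate 1). Re-isolated against cultured controls (7974) stayed within 1.5 times under each alternative run, and left-out libraries gave 6892 to 8109. For the difference of N1OE effects (475), array weights gave 1267, limma-voom 223, separate fits 749, marked controls alone 967 and unmarked ones 1546. Left-out libraries gave 240 (cultured N1OE replicate 3) to 501 (re-isolated control replicate 2).

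Replicate numbers showed no pairing that held throughout: in no comparison was every library closest to its own number. In culture 1 N1OE library was, and pairs of the same number reached r = 0.468. With so few libraries this check cannot rule a pairing out. With the number as a replicate block, re-isolated N1OE gave 445 genes by titles and 150 by descriptions, and N1KO 61 and 905. No block was fitted for the difference of effects.

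Of the lists called by camera at the preset correlation, an estimated correlation left 0 of 6 in cultured N1OE, 0 of 13 in re-isolated N1OE, 3 of 11 in N1KO, 2 of 11 in N1OE against N1KO, 0 of 13 between settings and 0 of 15 for the difference of effects. An estimate above 0.01 widens the variance of a list by construction. fry called 6, 2, 3, 4, 21 and 5 lists in the same order, of which 2, 2, 3, 3, 13 and 4 are shared with camera. Leaving out the 2 libraries of the other description form gave 11 lists in cultured N1OE, and unmarked controls alone 9 for the difference of effects. N1OE against N1KO had 7 lists without N1OE replicate 4. Over left-out libraries the number of called lists ran from 5 to 7, 12 to 16, 10 to 16, 7 to 13, 12 to 14 and 14 to 16 in the same order.

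Of 7257 values of named genes under alternatives 6342 kept direction and side of the threshold, 851 fell short of it, 50 newly passed and 14 turned direction. Of those 14, 2 passed: Nrarp in re-isolated N1OE against unmarked controls by header (-2.05) and Notch1 between settings with unmarked controls only (0.99). The others passed neither way: Nrarp in re-isolated N1OE with a pseudocount of 5 CPM (-0.074) and unmarked controls by description (-0.87), Hes5 there against unmarked controls (-0.54), and Nrarp in N1KO against marked controls by description (0.73) and header (1.01). Dtx1 in N1KO ran from -1.86 to 0.24 over left-out libraries (N1KO replicate 1 and 2). Notch1 between settings was 0.21 with median ratio scaling, 0.15 with array weights and -0.19 to 0.25 over left-out libraries (re-isolated control replicate 3 and 1), above 0 in 4 of these. Depth limits what can be said of genes under 3 reads.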

Other observations

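The comparison of observed and simulated effects was chosen after the result was seen, and so was the search for genes that part the controls from both engineered groups.

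A group of 8 genes lay higher in every re-isolated N1OE and N1KO library than in any of the 9 re-isolated controls, where they averaged under 1 CPM. Beside Otx2 (0.537 CPM in controls, 39.8 in N1OE and 18.95 in N1KO), the apelin receptor gene Aplnr measured 0.706, 12 and 10.1 CPM and Klf14, a transcription factor gene, 0.165, 17.6 and 3.97. Igsf23 measured 0.47, 17.9 and 20.5 CPM, and Slc26a8 0.119, 33.4 and 0.999. In culture Vat1l measured 63.3 ± 47.2 CPM in controls and 22.1 ± 7.25 in N1OE, which did not pass limma's test (adjusted p = 0.265).

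Against the unmarked controls, mean levels of marker lists in N1KO moved apart. Fibro-adipogenic markers averaged 7.04 in log2 CPM against 3.84 (6.09 ± 1.03 in the marked controls), tenocyte and chondrocyte markers 4.92 against 1.92 (2.59 marked), and endothelial markers 3.52 against 0.64 (0.69 marked), each with all 3 N1KO libraries above all 4 unmarked controls. Pericyte and smooth muscle markers averaged 4.25 against 4.73 (3.82 marked). Satellite cell markers averaged 6.18 against 6.74 (6.37 marked), with 2 of 3 N1KO libraries below all unmarked controls and 1 above.

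N1OE and N1KO share their controls, which by itself links the effects. Over all controls the effects correlated across genes with r = 0.0433, where simulations with shared controls gave 0.280 (genes are not independent replicates). The simulated groups held no real changes and no marked and unmarked sets, so the 2 values are not directly comparable. Of the called genes 11 were higher in both (2.5 by independence), 1 was lower in both (0.887) and 6 went opposite ways. With N1OE set against the marked and N1KO against the unmarked controls r was -0.342, with 18 higher in both (31.9 by independence), 7 lower in both (24.4) and 334 opposite. With the sets exchanged r was -0.249, with 15 higher in both (19.3), 5 lower in both (20.1) and 141 opposite.

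Other splits of the same libraries into groups of the same sizes tested whether chance can give as many genes. For cultured N1OE against control 1 of 35 splits, the real one, gave 1325 genes and the highest other gave 0. That is the smallest share that 35 splits can give. The splits also take the libraries as independent, which N1OE replicates 2 and 3 may not be (chi-square per degree of freedom 3.43). Without N1OE replicate 2 and 3 in turn the count was 164 and 158. The splits alone therefore do not exclude chance. The real split also gave the most genes for N1OE against N1KO (1 of 35, 1040 genes, highest other 43). So it did for re-isolated against cultured controls (1 of 100, 7974, highest other 2618). In these 2 comparisons the library set or the kit goes with the group. For the difference of N1OE effects 1 of 100 splits, the real one, gave 475 genes, but the highest other gave 382 with the 4 unmarked controls as its re-isolated group, which follows the library set. That real count was 240 and 262 without cultured N1OE replicate 3 and 2 and 223 with limma-voom. Each is below that split, but no splits were run for these other fits. For re-isolated N1OE, 2 of 100 splits gave as many as the real 1000, and the other, with 2383, set the 4 unmarked controls against the rest, so it follows the library set. For N1KO, 3 of 100 splits gave as many as the real 93, and the highest other gave 1575, which points to a structure of the samples (its group was control replicates 1, 7 and 8). Within the sets the counts are 1630 and 2731 for N1OE, 412 and 1013 for N1KO and 967 and 1546 for the difference of effects. Between marked and unmarked controls, 1 of 100 splits gave the real 3645 genes, and the highest other gave 2389.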
